A study of Mus musculus with 1922 samples.

How the data were processed

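The data were single-cell RNA-seq libraries from 1922 sorted myeloid cells of the mouse brain, made with Smart-seq2, a plate-based method that reads whole transcripts and carries no molecular identifiers. Per the labels, the cells came from C57BL/6N wild-type mice at embryonic day 14.5 (E14.5, 144 cells), postnatal day 7 (P7, 1048 cells) and postnatal day 60 (P60, 730 cells). The regions at P7 and P60 were the cortex (CTX), hippocampus (HIP), striatum (STR), cerebellum (CB), olfactory bulb (OB) and choroid plexus (CP), and the whole brain was taken at E14.5. The sort gates were CD45lowCD11b+, CD45hiCD11b+ (the only gate for CP) and, at E14.5, cKit-CD45+. Per the labels' protocols, tissue of 3 to 8 mice was pooled, E14.5 brains were dissociated through a needle, and P7 and P60 tissue was dounced in the cold and cleared of myelin on magnetic columns.

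Per the submitters' processing notes, reads were handled with Trim Galore 0.4.3, STAR 2.5.3a, Picard and HTSeq on the mouse build mm10. The annotation release and the counting options are not given in the sources used here. The authors deposited whole-number read counts per gene and cell, not normalized, in 1 table with 23337 gene rows and 92 rows of ERCC spike-in RNA. Column totals matched the total-count label in 1922 of 1922 cells, and detected genes matched their label in 1922 of 1922 cells when spike-in rows were left out. The table held 0 mitochondrially encoded rows, so the mitochondrial share was not analysed here. No pair of cells had identical counts. Per the labels, a cell passed quality control on total counts, detected genes and spike-in correlation: 1816 cells passed and 106 failed, and failed cells entered only the alternative that used all cells. Passed cells held a median of 552656 reads on genes (92237 to 2262218) and 1563 detected genes (329 to 5421), and spike-ins took a median of 13.8% of counts. Cells were sorted 1 to a well and doublets were not called, so attached cells are not excluded.

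The labels name no animal, so cells were not used as replicates. Gene counts of the passed cells were summed per age, region and gate into 23 pools of 9478293 to 86601890 reads, and the 5 brain regions served as the paired units. P-values therefore measure the spread between region pools, which may share mice. In the 5 brain regions each sequencing library held 1 age only, so the library and the age cannot be told apart there. Both CP ages shared 1 library.

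Counts of pools were tested with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, TMM scaling, its default filter on low counts) in R 4.3.3, with region as a block in the age and gate comparisons and age as a block in the region and CP comparisons. The Benjamini-Hochberg threshold was 0.05 over all tested genes. The interaction was the gate difference (CD45hi minus CD45low) at P7 minus that at P60. Lists of genes with 5 or more tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Of 402 list entries, 395 were found in the table, 5 of them under older symbols. The lists, the pools, the tests of the main comparisons, the thresholds for calling cells and the rule for naming genes were fixed before the data were examined. Tests and alternatives chosen later are named as such below. The disease-associated list comes from work on other samples but overlaps genes reported for these cells, so it is not independent of them. That rule named, per comparison, up to 6 genes each way with the largest log2 change among those past the threshold, with an average log2 CPM of at least 5 and the same direction in every region pair. It added members of the leading lists, and always P2ry12, Tmem119, Sall1, Mrc1, Spp1, Apoe, Mki67, Ccr2, S100a8 and Cd74. Levels are CPM of pools as mean ± SD over 5 pools. For log2 changes the value after ± is the standard error of the fit, and for shares of cells and their differences it is the SD over 5 regions. A fold against pools without any read was computed against a floor of 3 reads over the group and is written as "at least". Comparisons with 1 pool on a side carry no test. They used a rule of size: at least 50 CPM, and at least 4-fold away from the nearest pool or plate of the other side. Some genes that the rule or a list named are not reported here. For lists in these comparisons, the median was ranked among 10000 random lists matched on expression.

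Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (counts scaled to 10000, 2000 variable genes, 30 components, 15 neighbours, resolution 0.8). Clusters were given "-like" names from marker lists fixed in advance, and 2 clusters stayed unnamed (125 and 7 cells). The microglia-like class (1098 cells) holds a cycling cluster and 2 clusters led by disease-associated genes. For shares of cells, each cell was thinned to 200000 reads and shallower cells were left out (38 of 1816: 21 of P60 CD45hi, 8 of P7 CD45hi, 5 of P7 CD45low and 4 of P60 CD45low). A cell was called cycling with 3 or more of 10 cycle genes at 10 CPM or more, and disease-associated with 4 or more of Spp1, Gpnmb, Igf1, Itgax, Lpl, Clec7a, Lgals3 and Fabp5. Both calls divide a range: 52 cells had 2 and 33 had 3 cycle genes, and 111 had 3 and 61 had 4 disease-associated genes. As a background, 0 of 116 cells of a monocyte-like cluster (median 385819 reads) were called cycling and 0 of 33 neutrophil-like cells (median 277706 reads) were called disease-associated. Shares carry Clopper-Pearson intervals at 95% and were compared with an exact two-sided sign-flip permutation over 5 regions, in a family of 88 tests. With 5 regions the smallest p is 0.0625, so this test cannot reach 0.05. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

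The fits were tested on simulated counts drawn from the real pools with 200 genes changed. edgeR recovered 77.3% of the genes changed 16-fold and 44.8% of those changed 4-fold in the age comparison of CD45low pools. In that of CD45hi pools it recovered 40.9% and 8.96%. For the gates it recovered 97% and 68.7% at P7, and 34.8% and 5.97% at P60. The share of false calls by edgeR was 23.1% for the joint region test and 0% to 9.09% for the others, and by DESeq2 1.42.0 it was 52.1% to 85.7%. Alternatives were another scaling (RLE), DESeq2, no filter, all deposited cells, limma on the mean CPM per cell, a 1.5-fold minimum, a fit without the block, equal cell numbers per pool, subsets of cells or libraries (among them microglia-like cells without the cycling cluster and without the 2 clusters at resolution 1.2 led by S phase genes and by G2 and M phase genes), and each region left out in turn. Smart-seq2 does not mark strand, so overlapping and antisense genes are not separated. Gene coordinates are from GENCODE M21 (GRCm38, the same assembly as mm10), where 137 of 137 named genes were located, some through current symbols. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.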

Results

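The transcriptomes of 1922 single myeloid cells sorted from mouse brains at E14.5, P7 and P60 were compared by age, by sort gate and by region. The CD45lowCD11b+ gate is meant for microglia, the resident macrophages of the brain tissue, and the CD45hiCD11b+ gate for other myeloid cells. After quality control 1816 cells remained, in 1 pool at E14.5, 5 region pools per gate at P7 and at P60, and 1 choroid plexus pool at each of these ages. Pools held 9478293 reads (P60 STR, CD45hi, 29 cells) to 86601890 reads (E14.5). By their markers, the clusters were called microglia-like (1098 cells), border-macrophage-like (273 cells), monocyte-like (170 cells), dendritic-cell-like (88 cells), neutrophil-like (47 cells) and NK-cell-like (8 cells), and the rest stayed unnamed. Levels below are mean CPM ± SD over 5 region pools unless said otherwise.

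In the CD45low gate, P7 cells carried Mrc1, Igf1, Gpx3 and Spp1, which were near 0 at P60, and more Apoe, while Tmem119, Selplg, Cst3 and Hspa1a were lower than at P60. Mrc1, the macrophage mannose receptor, stood at 231.3 ± 57.07 at P7 and 0.0475 ± 0.106 at P60 (adjusted p = 0.00117). Igf1, a growth factor, stood at 90.71 ± 88.5 and Gpx3, an extracellular peroxidase, at 170.2 ± 129.2 at P7, each against 1 read in all P60 pools (adjusted p = 0.000153 for each). Apoe, the main lipid carrier of the brain, was higher at P7 (10280 ± 5546 against 1114 ± 1178, log2 change 3.57 ± 0.59, adjusted p = 0.03), with 3216 CPM in OB and 487.8 to 708.2 in the other P60 pools. Spp1, the secreted protein osteopontin, was at 774 ± 1407 against 1.705 ± 3.81 (adjusted p = 0.0316), with a spread wider than its mean. All of these were higher at P7 in 5 of 5 regions.

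Lower at P7 in 5 of 5 regions were Tmem119, a microglial membrane protein (2456 ± 1001 against 8437 ± 1237, log2 change -1.95 ± 0.30, adjusted p = 0.0272), and Selplg, the P-selectin ligand (1300 ± 499 against 6631 ± 628, log2 change -2.48 ± 0.24, adjusted p = 0.00389). Cst3, the protease inhibitor cystatin C, fell likewise (4267 ± 1936 against 18720 ± 4063, adjusted p = 0.00689). Hspa1a, a heat shock gene, had no read in P7 pools and was at 731.5 ± 563 at P60, at least 64200-fold higher there (adjusted p = 0.00117). Its reads can be shared with the near-identical Hspa1b. P2ry12 (5031 ± 1524 against 5486 ± 1280, adjusted p = 0.695), Cx3cr1 (12420 against 11820, adjusted p = 0.998) and Sall1 (335.4 against 422.9, adjusted p = 0.663) did not pass. Tmem119 (chromosome 5, 113793729 to 113800516) and Selplg (113818536 to 113832644) are close neighbours on mm10. Apoe lies on chromosome 7 (19696109 to 19699188), Mrc1 on chromosome 2 (14229392 to 14332057), Igf1 on chromosome 10 (87858265 to 87937042) and Hspa1a on chromosome 17 (34969190 to 34972156).

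Of 10466 genes tested with edgeR in this comparison, 59 passed as higher and 68 as lower at P7, each in the same direction in 5 of 5 regions, and the median log2 change of all genes was 0.13. Spike-ins took 8.08% to 14.2% of counts per P7 pool and 13.4% to 19.9% per P60 pool (medians over cells). Of 15 S phase genes 5 rose over all genes and 14 did adjusted over the list alone (camera adjusted p = 2e-14, adjusted p = 0.092 with an estimated correlation). Mcm6, a subunit of the replication helicase, was among them (326 ± 149.9 against 15.12 ± 12.2, adjusted p = 0.0328). Of 16 G2 and M phase genes 1 rose, and 14 adjusted over the list alone (camera adjusted p = 1.31e-13, adjusted p = 0.141 with an estimated correlation). Mki67, a proliferation marker, did not pass by itself (397.5 ± 208.1 against 21.83 ± 38.5, adjusted p = 0.169, higher in 5 of 5 regions). Of 20 homeostatic microglia genes 6 fell and 8 did adjusted over the list alone (camera adjusted p = 2.75e-09, adjusted p = 0.0685 with an estimated correlation), with Selplg, Cst3, Slc2a5, Olfml3 and Tmem119 among the 6. Of 18 disease-associated genes Igf1, Apoe and Spp1 rose, and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 5.73e-06, adjusted p = 0.141 with an estimated correlation). Apoe and Plin2, a lipid droplet protein, rose among 19 genes of lipid handling, and 9 did adjusted over the list alone (camera adjusted p = 1.28e-07, adjusted p = 0.0529 with an estimated correlation). Among 15 immediate early genes Jund and Btg2 fell, and 8 did adjusted over the list alone (camera adjusted p = 1.48e-07, adjusted p = 0.22 with an estimated correlation). Of 18 myeloid transcription factor genes 2 fell, Cebpb among them, and 9 did adjusted over the list alone (camera adjusted p = 4.45e-06, adjusted p = 0.0529 with an estimated correlation). The complement genes C1qa, C1qb and C1qc fell among 12 of their list, where adjusted over the list alone 2 rose and 6 fell (camera adjusted p = 0.00609, adjusted p = 0.106 with an estimated correlation). The count over both directions fell to 32 without CTX, 22 without HIP, 10 without STR, 52 without CB and 35 without OB, and to 40 in microglia-like cells without the S phase and the G2 and M phase clusters (38 of them among the reported calls). Of the 23 genes named by the rule that passed, 6 (among them Gpx3, Hspa1a, Mrc1, Selplg and Tgm2) passed with each region left out, whereas Apoe was lost without CTX, HIP, STR or CB (adjusted p of 0.00358 to 0.137), Spp1 without CTX, STR, CB or OB (0.00338 to 0.136) and Tmem119 without CTX, HIP or STR (0.0251 to 0.116). Igf1 was lost without CB (edgeR adjusted p = 0.062), Cst3 without STR (0.0544) and Mcm6 without CTX, HIP, CB or OB (0.0355 to 0.134). Jund was lost without CTX, STR or CB, Btg2 without CTX, HIP, STR or OB, and Plin2 and Cebpb with any region left out. DESeq2 called 941 genes higher and 503 lower, and limma 507 and 221. Each library of these regions held 1 age, so no value within a library could be had.

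Cycling cells were counted apart from the gene test. In the CD45low gate 26.4 ± 9.01% of cells were called cycling at P7 and 1.47 ± 2.26% at P60, a difference of 24.9 ± 9.51 points in 5 of 5 regions (exact sign-flip permutation p = 0.063, the smallest that 5 regions allow, adjusted p = 0.153). The P7 share was 37.5% in OB, 30.8% in STR, 29.3% in HIP, 18.6% in CTX and 15.8% in CB. In the CD45hi gate the share at P60 was 3.41 ± 3.45%, and that at P7 was above it in 4 of 5 regions without the test passing (exact p = 0.125). At E14.5 it was 30.3% (43 cells, 22.9% to 38.5%, Clopper-Pearson 95%).

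**Figure D1:**
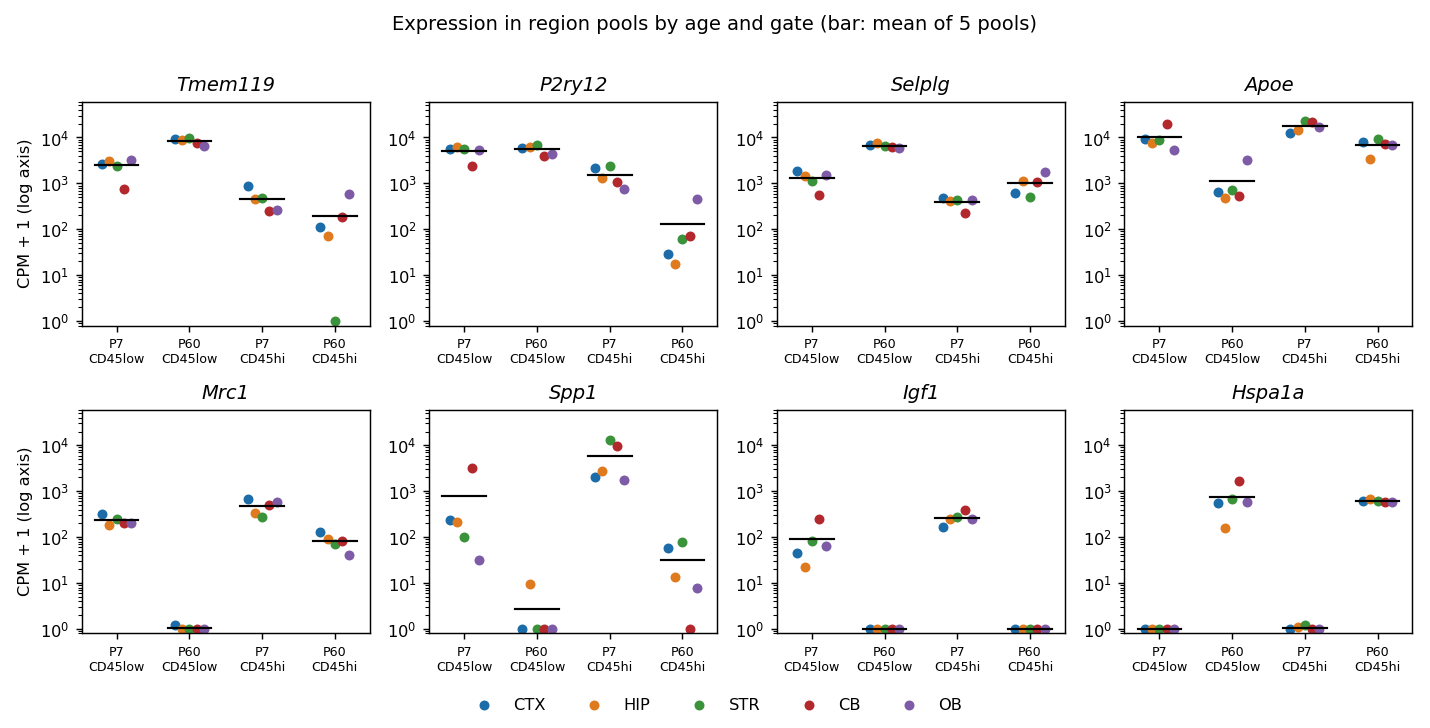
Levels of 8 genes in CPM + 1 on a log axis for P7 and P60 pools of both gates; points are 5 region pools per group and the bar is their mean. Tmem119 and Selplg had means of 8437 and 6631 in P60 CD45low pools against 2456 and 1300 in P7 CD45low pools, and Hspa1a was at 731.5 in P60 CD45low pools and without a read in P7 ones.

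In the CD45hi gate, P7 pools had more Gpnmb, Igf1, Abca1 and Ctsb, and P60 pools more Ly6c2, Hp, Il1b and Hspa1a. Gpnmb, a glycoprotein of lysosomes and membranes, was at 686.9 ± 496.9 at P7 and had no read at P60 (at least 17010-fold higher, adjusted p = 0.014), and Igf1 was at 264.1 ± 80.09 and at least 6541-fold higher (adjusted p = 0.0262). Abca1, a cholesterol exporter, was at 471.4 ± 199.7 against 9.016 ± 13 (adjusted p = 0.0344), with 32.1 CPM in OB and 0.5672 to 4.537 in the other P60 pools, and Ctsb, the protease cathepsin B, at 12460 ± 4273 against 2794 ± 415 (log2 change 2.09 ± 0.28, adjusted p = 0.0292). Higher at P60 were Ly6c2, a monocyte surface protein (29.78 ± 17.99 against 527 ± 139.4, log2 change -4.31 ± 0.48, adjusted p = 0.0213), Hp, the haemoglobin binder haptoglobin (112.4 ± 79.78 against 1150 ± 529.3, adjusted p = 0.014), and Il1b, a cytokine gene (29.94 ± 41.68 against 304.7 ± 122.4, adjusted p = 0.0499), where HIP carried most of the P7 mean and the other P7 pools had 5.109 to 19 CPM. Hspa1a was at 0.07116 at P7 and 616.8 ± 32.33 at P60 (adjusted p = 0.014), the same direction as in the CD45low gate. All were the same way in 5 of 5 regions. Reads of Ly6c2 can be shared with its copy Ly6c1. Gpnmb lies on chromosome 6 (49036546 to 49070929) and Ly6c2 on chromosome 15 (75108158 to 75111970).

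The makeup of this gate moved with age as well, so for the genes above a change of makeup and a change within cells cannot be told apart. Monocyte-like cells were 15.6 ± 6.84% of cells at P7 and 52.7 ± 18.8% at P60, and neutrophil-like cells 1.53 ± 1.47% and 20 ± 7.94% (exact permutation p = 0.063 for each, 5 of 5 regions, adjusted p = 0.153). NK-cell-like cells were 0% and 4.25 ± 3.21% (exact p = 0.125, 4 of 5 regions). Dendritic-cell-like cells were 12.4 ± 13.2% and 9.63 ± 3.99% (exact p = 0.688). Microglia-like cells made up 85.3% of the P7 pool of CB, 88.1% of STR, 63.8% of CTX, 43.2% of HIP and 24.4% of OB, but 23.7% of OB (9 of 38 cells) and 3.45% of STR at P60, and 0 cells of the other P60 brain pools. In the CD45low gate none of these other classes was found at either age. These are shares of sorted cells, and gate settings that differ between sorts were not tested.

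Of 10421 genes 62 passed between the ages in this gate (26 higher and 36 lower at P7), while the median of all genes was 0.84 on the log2 scale. The ages also parted in RNA content without overlap: spike-ins took 5.8% to 14.9% of counts per P7 pool and 17.6% to 32.7% per P60 pool (medians over cells), and cells had a median of 1628 to 2653 detected genes at P7 and 915 to 1472 at P60. Of 15 immediate early genes 6 fell, and 11 adjusted over the list alone (camera adjusted p = 7.33e-17, adjusted p = 0.112 with an estimated correlation), with Fos at 216.4 ± 112.8 against 1392 ± 520.8 (adjusted p = 0.0262). Of 15 monocyte genes Hp and Ly6c2 passed and 12 fell adjusted over the list alone (camera adjusted p = 7.63e-19, adjusted p = 0.213 with an estimated correlation). Ctsb, Grn and Ctsz rose among 23 lysosome genes, where 20 rose adjusted over the list alone (camera adjusted p = 2.86e-08, adjusted p = 0.213 with an estimated correlation). Of 10 MHC class I genes 3 fell, and 6 adjusted over the list alone (camera adjusted p = 4.54e-08, adjusted p = 0.213 with an estimated correlation). Of 15 interferon genes Ifitm3 and Ifi27l2a fell, and 6 adjusted over the list alone (camera adjusted p = 1.56e-10, adjusted p = 0.213 with an estimated correlation). Of 19 disease-associated genes Gpnmb, Igf1, Ctsb, Cd9 and Apoe rose, while adjusted over the list alone 12 rose and 3 fell (camera adjusted p = 0.0319, adjusted p = 0.26 with an estimated correlation). None of 80 ribosomal protein genes, 11 neutrophil genes or 8 MHC class II genes passed, although the camera test called each list lower at P7 (adjusted p = 1.91e-20, 4.07e-10 and 3.64e-07, and adjusted p = 0.213 with an estimated correlation for each). For inflammatory, complement and transcription factor lists the median was above 0 and the camera direction down, and none was called (adjusted p = 0.144, 0.855 and 0.23). The count fell to 5 without CTX, 0 without HIP (edgeR), 7 without STR, 8 without CB, and rose to 55 higher and 69 lower without OB. All 22 named genes that passed were lost with at least 1 region left out, Gpnmb, Hp and Hspa1a only without HIP (adjusted p = 0.0641, 0.0641 and 0.066). Il1b was lost without any 1 of the 5 regions (adjusted p of 0.088 to 0.19), and Abca1 without CTX, HIP, STR or CB (0.00745 to 0.188), with a log2 change of 7.60 in place of 6.85 without OB. DESeq2 called 2616 genes higher and 568 lower, limma 962 and 227, and the fit without the region block 390 and 197.

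At P7 the CD45hi pools had more Plbd1, F13a1, Ccr2, S100a8, Clec7a and Lgals3 than the CD45low pools of the same regions, and less Tmem119, P2ry12 and Selplg. Plbd1, a phospholipase-like gene, was at 345 ± 244.8 and F13a1, a clotting factor subunit, at 156.5 ± 177, against 1 read each in the CD45low pools (adjusted p = 5.99e-06 for each). Ccr2, the chemokine receptor of monocytes, stood at 292.1 ± 257.4 against 0.05782 (adjusted p = 0.00615), and S100a8, a calcium-binding protein of neutrophils and monocytes, at 179.8 ± 205.8 against 1 read (adjusted p = 8.96e-06). Clec7a, the pattern receptor dectin-1, was at 262.6 ± 82.94 against 35.82 ± 22.87 (log2 change 3.11 ± 0.34, adjusted p = 0.00569), and Lgals3, galectin-3, at 402.3 ± 149.1 against 16.29 ± 19.64 (adjusted p = 0.0198). Lower in the CD45hi pools were Tmem119 (463.4 ± 251.7 against 2456 ± 1001, log2 change -2.31 ± 0.31, adjusted p = 0.0126), P2ry12 (1543 ± 701 against 5031 ± 1524, adjusted p = 0.0413) and Selplg (398.3 ± 97.4 against 1300 ± 499, adjusted p = 0.0072). Each of these held in 5 of 5 regions. Apoe (17820 against 10280, adjusted p = 0.157), Mrc1 (474.6 against 231.3, adjusted p = 0.0831), Spp1 (5870 ± 5195 against 774 ± 1407, adjusted p = 0.0619) and Cd74 (1849 against 119.8, adjusted p = 0.262) did not pass. Clec7a lies on chromosome 6 (129461591 to 129472779) and Lgals3 on chromosome 14 (47367751 to 47386160).

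Of 11087 genes 81 passed at P7 (74 higher and 7 lower in CD45hi). Of 13 monocyte genes 7 rose, and 13 adjusted over the list alone (camera adjusted p = 4.19e-21, adjusted p = 0.234 with an estimated correlation). Tmem119, P2ry12 and Selplg fell among 20 homeostatic genes, and 14 fell adjusted over the list alone (camera adjusted p = 6.57e-19, adjusted p = 0.234 with an estimated correlation). Clec7a, Lyz2 and Lgals3 rose among 19 disease-associated genes, and 12 rose adjusted over the list alone (camera adjusted p = 3.38e-12, adjusted p = 0.234 with an estimated correlation). Of 11 border macrophage genes 2 rose, and 9 adjusted over the list alone (camera adjusted p = 1.1e-10, adjusted p = 0.234 with an estimated correlation). Of 16 G2 and M phase genes 1 fell, and 9 adjusted over the list alone (camera adjusted p = 4.65e-12, adjusted p = 0.247 with an estimated correlation). H2-Aa was 1 of 2 among 7 MHC class II genes that rose (camera adjusted p = 1.45e-05, adjusted p = 0.25 with an estimated correlation), and 5 rose adjusted over the list alone. Leaving out CTX, HIP, STR, CB or OB gave 49, 25, 60, 90 and 38 genes, and 10 of 19 named calls held each time. Tmem119 and Selplg were lost without HIP (adjusted p = 0.11 and 0.0664), Lgals3 without HIP, STR or OB, and P2ry12 with any region left out. Where both gates shared a library (OB, STR and HIP) 29 genes passed, 20 of them among 78 tested calls, and Tmem119 (log2 change -2.99, adjusted p = 0.149) and Clec7a (6.16, adjusted p = 0.393) kept their direction without passing. DESeq2 called 631 genes higher and 260 lower, and limma 252 and 93.

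At P60 the gates stood farther apart. S100a8 (2526 ± 1556) and S100a9 (2552 ± 1523) each had 1 read in all CD45low pools (adjusted p = 1.52e-05 for each), and the neutrophil granule gene Lcn2 (1253) had none, a difference of at least 80350-fold (adjusted p = 0.00113). Itgal, an integrin of leukocytes, was at 1006 ± 484 and at least 64510-fold higher in CD45hi pools (adjusted p = 0.00123). Apoe was at 6938 ± 2240 against 1114 ± 1178 (log2 change 3.04 ± 0.43, adjusted p = 0.00711), Mrc1 at 82.98 ± 32.8 against 0.0475 (adjusted p = 0.00652) and H2-Aa at 2445 ± 801 against 4.198 ± 9.39 (adjusted p = 0.0199). P2ry12, a nucleotide receptor of microglia, was lower in CD45hi pools (126.7 ± 187.6 against 5486 ± 1280, log2 change -6.59 ± 0.90, adjusted p = 0.00923). Its CD45hi level was 460 CPM in OB, which held most microglia-like cells of these pools, and 16.41 to 69.45 in the other regions, and without OB the log2 change was -7.27. Slc46a1, a folate transporter, had no CD45hi read against 292 ± 74.83 (at least 7232-fold lower, adjusted p = 0.0039). Ctsd, cathepsin D, was at 2074 ± 2034 against 18690 ± 1555 (adjusted p = 0.00786). All held in 5 of 5 regions, as did Tmem119, which did not pass (189.4 ± 228.5 against 8437 ± 1237, adjusted p = 0.1025). P2ry12 lies on chromosome 3 (59216272 to 59262871), S100a8 also on chromosome 3 (90668978 to 90670035) and H2-Aa on chromosome 17 (34282744 to 34287823).

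Of 9641 genes 544 passed at P60 (330 higher and 214 lower in CD45hi), with the median of all genes at -0.61. All 15 monocyte genes rose (camera adjusted p = 4.29e-22, adjusted p = 0.00959 with an estimated correlation), and 15 did adjusted over the list alone. Of 8 neutrophil genes 7 rose, also 7 adjusted over the list alone (camera adjusted p = 6.4e-12, adjusted p = 0.0864 with an estimated correlation). Of 8 MHC class II genes 5 rose, and 6 adjusted over the list alone (camera adjusted p = 6.78e-08, adjusted p = 0.0532 with an estimated correlation). Of 20 homeostatic genes 12 fell, and 20 adjusted over the list alone (camera adjusted p = 5.49e-14, adjusted p = 0.118 with an estimated correlation). Of 22 lysosome genes 12 fell, while adjusted over the list alone 1 rose and 17 fell (camera adjusted p = 3.81e-08, adjusted p = 0.118 with an estimated correlation). Of 80 ribosomal protein genes 14 rose, and 35 adjusted over the list alone (camera adjusted p = 2.12e-20, adjusted p = 0.143 with an estimated correlation). Among 17 disease-associated genes 4 rose and 4 fell (camera adjusted p = 0.00415, adjusted p = 0.149 with an estimated correlation), and 6 rose and 5 fell adjusted over the list alone. With CTX, HIP, STR, CB or OB left out the counts were 213, 256, 302, 254 and 350, and 17 of 26 named calls held each time. Sall1, a microglial transcription factor (10.75 ± 24 against 422.9 ± 127.4, adjusted p = 0.0471), was lost without CTX, HIP, STR or CB, and H2-Aa without CTX, STR or CB. Cd74, the MHC class II invariant chain (4292 ± 1283 against 15.57 ± 13.7, adjusted p = 0.0426), was lost without HIP, STR, CB or OB, and Mrc1 without CTX. In the library that held both gates of CB and OB, 23 genes passed, 22 of them among the 508 calls tested there, with Hp, Cd74 and H2-Aa included, whereas P2ry12 had a log2 change of -8.51 without passing (adjusted p = 1). DESeq2 called 941 genes higher and 2057 lower, and limma 633 and 1061, the reverse of the balance above.

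The gate difference itself changed with age for 198 of 11764 genes (167 with a higher and 31 with a lower difference at P7). The CD45hi pools held microglia-like cells in every region at P7 but, in most regions, few or none at P60. A change in the makeup of the gate and a change within cells cannot be told apart here. Slc46a1 went from 292 in CD45low and 0 in CD45hi pools at P60 to 182.1 and 95.66 at P7 (interaction 15.66 on the log2 scale, adjusted p = 0.00015). Itgal went from 0 and 1006 to 17.63 and 279.3 (-14.35, adjusted p = 0.000122), and Mrc1 from 0.0475 and 82.98 to 231.3 and 474.6 (-10.66 ± 0.94, adjusted p = 0.00015, -13.49 without CTX). P2ry12 went from 5486 and 126.7 to 5031 and 1543 (4.89 ± 0.89, adjusted p = 0.0208, 5.85 without OB), and Ctsd from 18690 and 2074 to 10370 and 11400 (4.09 ± 0.62, adjusted p = 0.00777). Of 20 homeostatic genes 9 had a higher difference, and 20 adjusted over the list alone (camera adjusted p = 2.27e-15, adjusted p = 0.136 with an estimated correlation). Of 23 lysosome genes 8 did, and 16 adjusted over the list alone (camera adjusted p = 3.87e-12, adjusted p = 0.136 with an estimated correlation). The median over all genes was 0.84. Tmem119 (4.09, adjusted p = 0.275), Apoe (-2.10, adjusted p = 0.0535) and Spp1 (-4.64, adjusted p = 0.483) did not pass. The counts were 59, 41, 64, 39 and 239 without CTX, HIP, STR, CB and OB. P2ry12 and Sall1 were lost without CTX, HIP, STR or CB, and 6 of 19 named calls held each time, among them Mrc1, Slc46a1 and Itgal. Slc46a1 lies on chromosome 11 (78465697 to 78472059) and Itgal on chromosome 7 (127296260 to 127335138).

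Cells with disease-associated genes were counted per region. At P7 they made up 33.1 ± 19.9% of CD45hi and 8.15 ± 10.9% of CD45low cells, a difference of 25 ± 13.2 points in 5 of 5 regions (exact permutation p = 0.063, the smallest possible, adjusted p = 0.153). The CD45hi shares were 61.3% in CB (46 of 75 cells), 46.6% in STR (27 of 58 cells), 21.8% in OB, 20.8% in HIP and 15.2% in CTX. In the CD45low gate CB had 27.6% and the other regions 2.33% to 4.88%. At P60 the shares were 0.541 ± 1.21% and 0%, where 0 of 57 to 91 cells per CD45low pool allow a share of up to 3.3% to 5.26%, and P7 choroid plexus had 2.5%. The share was higher in CD45hi cells in 4 of 4 pairs of gates that shared a library (OB, STR and, in 2 libraries, HIP). At E14.5 it was 3.52%.

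**Figure D2:**
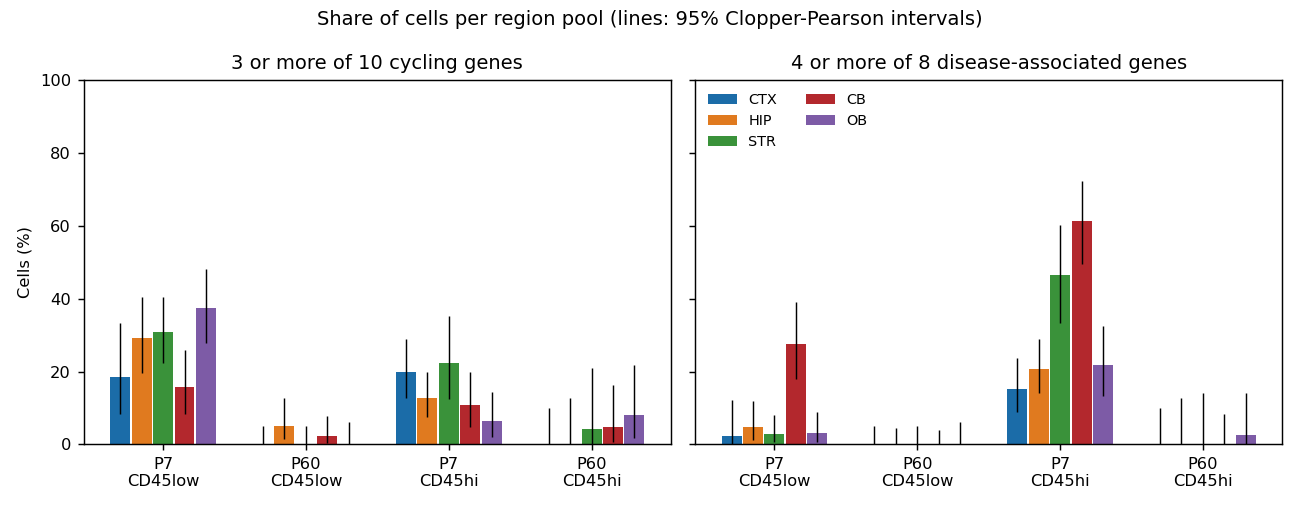
Percent of thinned cells per region pool called cycling (3 or more of 10 genes) or disease-associated (4 or more of 8 genes); lines are Clopper-Pearson 95% intervals. Cycling shares of P7 CD45low pools lie between 15.8% and 37.5%, and disease-associated shares of P7 CD45hi pools between 15.2% and 61.3%.

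Within the microglia-like class alone, P7 CD45hi cells had more Clec7a (246.4 ± 95.3 against 38.52 ± 28.2, log2 change 2.91 ± 0.35, adjusted p = 0.0335), Gpx3 (625.5 ± 61.4 against 155.1 ± 106.1, adjusted p = 0.0347) and Atp6v0d2, a proton pump subunit (93.97 ± 70.5 against 0.03483, adjusted p = 0.0335). They had less Tmem119 (638 ± 316 against 2466 ± 997, adjusted p = 0.0335), Selplg (362.9 ± 118.7 against 1315 ± 495.6, adjusted p = 0.0335) and P2ry12 (2115 ± 655 against 5074 ± 1481, log2 change -1.16 ± 0.14, adjusted p = 0.0335), each in 5 of 5 regions. Most CD45low cells of this class lay in a cluster led by Mcm6 and Mcm5, and many CD45hi cells in one led by Gpnmb and Spp1. Of 10671 genes 10 passed (7 higher, 3 lower). Of 19 disease-associated genes Clec7a rose, and 17 did adjusted over the list alone (camera adjusted p = 7.26e-20, adjusted p = 0.134 with an estimated correlation). Among 15 glycolysis genes 0 passed in edgeR and 10 rose adjusted over the list alone (camera adjusted p = 2.4e-12, adjusted p = 0.112 with an estimated correlation). Of 20 homeostatic genes 3 fell, and 9 adjusted over the list alone (camera adjusted p = 3.32e-10, adjusted p = 0.112 with an estimated correlation). The call is fragile: edgeR called 0 genes without CTX, HIP, STR or OB and 7 without CB, with 778 genes at an unadjusted p under 0.05 in the full set, and DESeq2 called 451 and limma 42 genes. It called 2 genes where both gates shared a library, 1 without the region block, and 0 without the clusters led by disease-associated genes.

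Between the 5 regions no gene of CD45low cells passed. edgeR called 0 of 11914 genes in the joint test (160 at an unadjusted p under 0.05), DESeq2 32, and limma 0 (439 at an unadjusted p under 0.05). Single regions against the rest gave 0 genes each, with 473, 346, 265, 456 and 324 at an unadjusted p under 0.05 for CTX, HIP, STR, CB and OB. The means of the 2 ages for Apoe were 10160 in CB and 4090 to 5035 in the other regions, for Spp1 1643 in CB and 15.27 to 119.3 elsewhere, and for P2ry12 3125 in CB and 4940 to 6238 elsewhere (adjusted p = 1 for each). The 2 pools per region came from different ages, and the high CB means of Apoe and Spp1 came from P7. At P7 Apoe was at 19810 in CB and 5453 to 9431 elsewhere, and Spp1 at 3287 and 30.53 to 238.6. At P60 Apoe was highest in OB (3216, against 487.8 to 708.2 in the other regions, CB included), and Spp1 was at 1.705 ± 3.81 over the 5 pools.

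Choroid plexus CD45hi cells, compared with those of the 5 brain regions over both ages (2 against 10 pools), had more Mrc1, Apoe and Ttr and less Hp and Ly6c2. Mrc1 was at 2145 ± 836 against 278.8 ± 235.7 (log2 change 3.51 ± 0.39, adjusted p = 0.000467, 10 of 10 pools) and Apoe at 36880 ± 6533 against 12380 ± 6586 (1.85 ± 0.36, adjusted p = 0.0268). Ttr, the transthyretin gene that plexus epithelium expresses, was at 1643 ± 106.2 and had no read elsewhere (at least 186200-fold, adjusted p = 0.000112). No choroid plexus read was found for Hp (631.3 ± 653 elsewhere, at least 28060-fold lower, adjusted p = 6.65e-05) or Ly6c2 (278.4 ± 278, at least 12370-fold lower, adjusted p = 1.35e-05). P2ry12 (adjusted p = 0.908) and Tmem119 (adjusted p = 0.906) did not pass, with log2 changes of 1.12 and 1.53. Ttr, Kcnj13, Aqp1 and Enpp2 rose among 7 epithelial genes, and 7 did adjusted over the list alone (camera adjusted p = 3.58e-21, adjusted p = 0.00625 with an estimated correlation). Of 15 monocyte genes 6 fell, and 12 adjusted over the list alone (camera adjusted p = 1e-31, adjusted p = 0.0207 with an estimated correlation). Among 15 immediate early genes Zfp36 fell, and adjusted over the list alone 1 rose and 10 fell (camera adjusted p = 1.98e-13, adjusted p = 0.0338 with an estimated correlation). Of 14 border macrophage genes Mrc1 rose, and 9 did adjusted over the list alone (camera adjusted p = 2.13e-05, adjusted p = 0.0817 with an estimated correlation). Lists for neurons (adjusted p = 0.211), astrocytes (0.861), oligodendrocytes (0.211) and endothelium (0.17) were not called. In all, edgeR called 87 of 13176 genes higher and 58 lower. Without CTX, HIP, STR, CB, OB, P7 CP and P60 CP the counts were 28, 37, 74, 53, 36, 94 and 14. Mrc1 was lost without P60 CP (log2 change 2.39, adjusted p = 0.156, against 4.22 without P7 CP) and Apoe without CTX, HIP, CB, OB or P60 CP (log2 change 0.69 without P60 CP and 2.59 without P7 CP), while Ttr, Hp and Ly6c2 held each time. Enpp2 was lost without CTX, STR, CB or OB, with a log2 change of 8.29 without P60 CP and 20.11 without P7 CP. Zfp36 was lost without CTX, HIP, STR or OB. The choroid plexus had a library of its own, which cannot be told apart from the tissue, and limma called 484 genes. Border-macrophage-like cells were 90.6% of choroid plexus cells at P7 (84.1% to 95%, Clopper-Pearson) and 81.6% at P60 (74.2% to 87.6%). Mrc1 lies on chromosome 2 and Ttr on chromosome 18 (20665280 to 20674321).

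With age several MHC class II genes were among the largest differences between the choroid plexus pools, here without a test, since each age is 1 pool of 2 plates in 1 library. H2-Ab1 was at 4.849 CPM at P7 and 5009 at P60 (663.2-fold between the nearest plates), H2-Aa at 6.023 and 2974 (289.3-fold), H2-Eb1 at 0.4865 and 2092 (2551-fold), Cd74 at 99.34 and 7722 (77.74-fold between the pools), and Ciita, the master regulator of these genes, had no read at P7 and 108.7 at P60 (at least 812.5-fold). Higher at P7 were Lyve1, a hyaluronan receptor (199.4 against 1.993, 50.97-fold between the nearest plates), and Slc40a1, the iron exporter (2362 against 122.4, 9.551-fold). Mrc1 was at 2736 and 1554, Apoe at 32260 and 41500, and Spp1 at 1018 and 39.68, with P7 plates from 153.8 to 1567. In all, 61 genes met the rule of size, 22 higher at P7 and 39 at P60. The median log2 ratio of 8 MHC class II genes was -6.52, below that of 10000 random lists, and that of 14 border macrophage genes was 0.82 (12 higher at P7, percentile 100). Dendritic-cell-like cells, whose cluster carries MHC class II genes, were 0 of the P7 cells (which allows a share of up to 2.36%) and 4.26% of the P60 cells (6 cells, 1.58% to 9.03%), and 7 dendritic cell genes had a median log2 ratio of -2.13. Within border-macrophage-like cells 78 genes met the rule, 51 of them shared, among these H2-Ab1 (4.607 and 4885 CPM), H2-Aa, H2-Eb1, Cd74, Ciita, Lyve1 and Slc40a1. H2-DMa and H2-Oa of the MHC class II list met it in neither set, and H2-Oa ran the other way within border-macrophage-like cells (8.382 CPM at P7, 3.68 at P60). Those cells lay mostly in a cluster led by Ttr, the epithelial gene, with Pf4 and Ednrb at P7 (80.3% of cells) and in one led by Siglec1 and Cd72 at P60 (72.3%). At resolution 1.2, 23 choroid plexus cells of this class formed a cluster of their own led by the epithelial genes Enpp2 and Ttr. H2-Ab1 (34257689 to 34269419) and H2-Eb1 (34305867 to 34316674) lie on chromosome 17, Cd74 on chromosome 18 (60803848 to 60812652), Ciita on chromosome 16 (10480059 to 10528418) and Lyve1 on chromosome 7 (110850607 to 110863239).

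**Figure D3:**
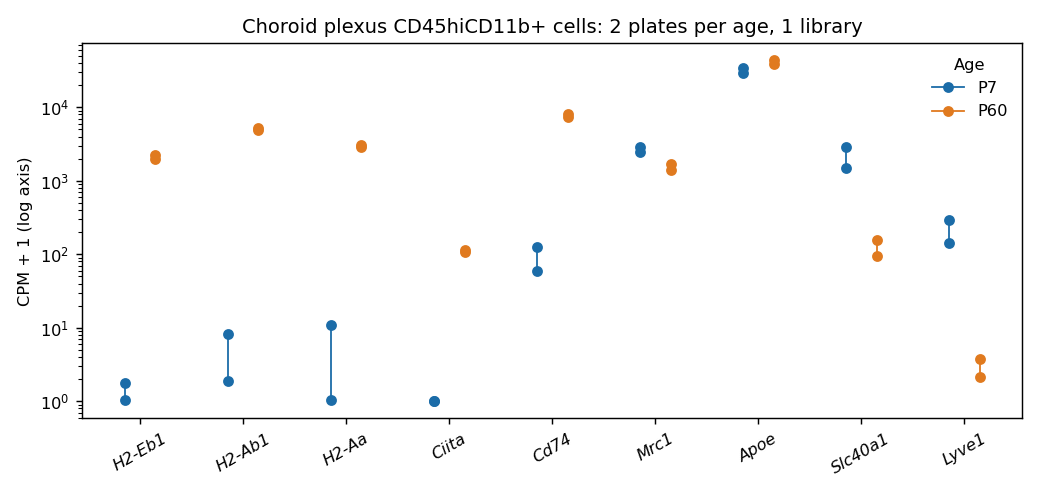
Levels of 9 genes in choroid plexus CD45hi cells in CPM + 1 on a log axis, with 2 plates per age from 1 library as points and no replicate animals. The pools went from 4.849 to 5009 CPM for H2-Ab1 and from 199.4 to 1.993 CPM for Lyve1 between P7 and P60.

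The single E14.5 pool was set beside the 10 CD45low pools of P7 and P60, without a test and with another sort gate and dissociation. Of its cells 34.5% (49 cells, 26.7% to 42.9%) were microglia-like and 62% (88 cells, 53.5% to 70%) lay in an unnamed cluster led by Mtap1b and Meg3, whereas the microglia-like share of the CD45low pools was 82.9% to 100%. The unnamed cells are not thereby shown to be other cells than microglia. P2ry12 was found at 10 CPM or more in 76.8% of all E14.5 cells, so cells of that cluster carried it too. P2ry12 was at 2237 CPM (Poisson interval 2227 to 2247) in 76.8% of cells, just under the lowest postnatal pool (2342), and Tmem119 at 1038 in 57.8%, within the postnatal range (767.1 to 9534, mean 2456 at P7 and 8437 at P60). Of the homeostatic microglia list, 0 of 20 genes were above the mean of the postnatal pools (median log2 ratio -1.22, percentile 0 of 10000 random lists). All 16 S phase and 16 G2 and M phase genes were higher than that mean (medians 0.81 and 1.08, percentile 100 for each), in which the P60 pools held few cycling cells. Mki67, a marker of cycling, was at 240.4 at E14.5 against 397.5 ± 208.1 at P7 and 21.83 ± 38.53 at P60, and the share of cycling cells was 30.3% at E14.5 and 26.4 ± 9.01% in P7 CD45low pools. Also higher than the mean were 13 of 15 glycolysis genes (1.17) and 77 of 79 ribosomal protein genes (0.84). Immediate early genes were lower (-2.95, 2 of 15 higher). Apoe was at 11970, Spp1 at 915.7 and Mrc1 at 114.9. By the rule of size 14 genes stood apart from each of the 10 pools, 8 higher and 6 lower. Xist, the RNA of the inactive X chromosome, was at 265.7 against at most 0.02523 in any postnatal CD45low pool and lies on chromosome X (103460366 to 103483254). Pmp22, a membrane protein, was at 19.12 against means of 184.5 at P7 and 600.5 at P60, and Fcgr2b, the inhibitory Fc receptor, at 31.02 against at least 193.1. With microglia-like cells alone 3 genes stood apart, and 297 did against P7 cells of the same library, 11 of them shared.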

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

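Chosen only after the result was seen were the 3 tests on other splits of the pools for the age comparisons and for the gates at P7, and the tests on cycling cells, on other cell types and on depth, and those of the library for genes of 1 direction or single regions. Values far from the other 4 pools of a group were sought in 183 groups by the gap to the nearest pool over the range, and 24 were found; chance marks about 1 in 20 groups. That rate does not hold where 4 pools have no reads or cells, since the ratio is then 1 whatever the fifth holds.

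Genes called between P7 and P60 in CD45low cells can reflect age or the sequencing library, since each library of these regions held 1 age. In the choroid plexus, where 1 library held both ages, 69.7% of the called genes measured there (83 genes) pointed the same way, above all of 10000 random sets (median 48.7%), and so did 71.7% in border-macrophage-like cells alone, which leaves out a microglia-like share of 5.51% at P7 and 11.3% at P60. This argues against the library as the whole cause only for genes lower at P7 (49 of 64, 76.6%, random median 40.6%, median log2 ratio there -0.566), while for genes higher at P7 (34 of 55, 61.8%, random median 58.2%, median log2 ratio 0.213) library and age cannot be told apart. Cycling cells stay open as part of it: in microglia-like cells without the S phase and the G2 and M phase clusters 38 of these genes stayed called, and the median log2 change of all of them that were tested was 1.56 against 1.75 in all cells, but pools shrank to as few as 33 cells. An effect of age stays a hypothesis, untested apart from library in the brain regions.

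Hspa1a was high in every P60 brain pool and near 0 at P7 in both gates. Handling of the P60 brain tissue before lysis is a candidate explanation: 54.3% of monocyte-like cells of the P60 brain pools (51 of 94) had it at 10 CPM or more, close to 44.7% of microglia-like cells (169 of 378), against 2.61% of P60 choroid plexus border-macrophage-like cells (3 cells) and 2.56% of P60 neutrophil-like cells (1 of 39). Reads shared with Hspa1b cannot make it, since the lowest P60 brain pool had 709 times the summed level of both genes in the highest P7 pool (170.7 against 0.2406 CPM). The number of libraries with brain cells of both ages was 0, so library and age cannot be told apart for this gene. Age as a biological cause of the Hspa1a difference stays open and untested. At resolution 1.2, 1 cluster was led by Hspa1a, Egr1 and Fos, with Jun, Btg2, Dusp1 and Jund among its top genes. Immediate early genes were lower at P7 in both gates. Handling was not tested for them, so it stays open there too.

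Disease-associated genes marked more P7 CD45hi than CD45low cells. Among microglia-like cells alone the lowest of the 5 regional differences was 20.1 points (mean 41.8 ± 19.1, exact permutation p = 0.063). That class includes the clusters led by Gpnmb and Spp1, genes of the call itself, so cells that carry them enter it whatever their type. Other cell types in the gate are therefore not excluded. In 4 of 4 region and library pairs the share was higher in CD45hi. This argues against the library as the whole cause in OB (21.8 points) and STR (42.8 points). The library stays open in HIP, where the intervals overlapped in both libraries (8.99 and 16.7 points). It also stays open in CTX and CB, where 0 libraries held both gates. In all 4 pairs each gate had a plate of its own, so gate and plate cannot be told apart. Sequencing depth is excluded as the whole cause in HIP and OB, where CD45hi cells had fewer reads (medians 493423 against 763519 and 488732 against 742763) and yet a share higher by at least 15.9 points. In CTX, STR and CB thinning to 1 depth hardly moved the mean difference (30.1 against 29.5 points). At this equal depth the intervals of the gates lay apart in STR (33.3% to 60.1% against 0.582% to 7.98%) and CB (49.4% to 72.4% against 18% to 39.1%). This argues against the number of reads as the whole cause in STR and CB, by intervals that count cells of 1 pool per gate. Thinning levels reads only. Before it, CD45hi cells there had more detected genes than CD45low cells (medians of 2653 against 1877 in CB and 2237 against 1760 in STR). An effect of that difference on the call was not tested. In CTX the intervals overlapped (8.97% to 23.6% against 0.0589% to 12.3%), so depth stays open there. A state in which cells carry more CD45 together with these genes may exist, as a hypothesis found and tested on the same data, beside gate settings that differ between sorts, which were not tested.

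For the interaction the units are the 10 combinations of region and age, not paired in the fit. Of 50 splits 1, the real one, gave as many as 198 genes, and the highest other gave 0. This argues against a chance split of these pools. Pools of 1 age may share mice, and each library of these regions held 1 age. Chance between animals and an effect of the library are therefore not excluded. The age and gate comparisons pair the pools by region. Only 16 splits exchange the groups within regions and so keep every pair parted, which is too few for a share under 0.05, and the highest other count among them was 0 genes (edgeR) in each comparison. Splits that ignore the pairing are weaker by design, since a region whose 2 pools stay together adds nothing. Of 100 such splits 1, the real one, was as large for age in CD45low pools (59 genes higher and 68 lower, highest other 37), for the gates at P7 (81 genes, highest other 1) and at P60 (544 genes, highest other 0). For age in CD45hi pools 5 of 100 gave as many as the real 62 genes, up to 75. The other 4 parted the pools of STR alone and kept both pools of each other region together, which with the region block is the same fit each time. Within microglia-like cells 7 of 100 splits gave as many as the real 10 genes. The other 6 parted the pools of OB alone and gave 273 genes. Chance is thus not excluded for this comparison or for age in CD45hi pools.

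Olfactory bulb stood above the other P60 CD45hi pools for P2ry12 (460 against 16.4 to 69.5 CPM, ratio 0.88), Sall1 (1), Slc2a5 (1), Sepp1 (0.944), Grn (0.878), Abca1 (0.874) and the disease-associated share (1, at 2.7% against 0%, which is 1 cell of 37). The other 4 pools had no read of Sall1 and at most 0.1415 CPM of Slc2a5. This pool held 9 microglia-like cells of 38. Hippocampus had the highest Gcnt2 of this group (0.86). Among P60 CD45low pools the highest were OB for Apoe (0.919, 3216 CPM), HIP for H2-Aa (1), Rrm2 (1), both without reads in the other 4, and Mki67 (0.773), and CB for Ifi27l2a (0.776). Among P7 CD45hi pools the highest were OB for F13a1 (0.799) and H2-T23 (0.768) and HIP for Il1b (0.86), and CB was lowest for Selplg (0.722). Cerebellum was highest among P7 CD45low pools for Spp1 (0.936, 3287 against 30.5 to 239 CPM), Gpx3 (0.89), Plin2 (0.808), Igf1 (0.734), Apoe (0.723) and the disease-associated share (0.899, 27.6%), and lowest for P2ry12 (0.832, 2342 against 5470 to 6103 CPM).

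The gate difference changed with age, by the interaction term, for 19 genes named by the rule. The log2 interaction was 19.63 for Mlph, 15.66 for Slc46a1, 15.12 for Agmo, 14.9 for Tspan9, 14.61 for Cables1, 13.9 for Tfpi, 11.65 for Slc2a5, 11.16 for Sall1, 4.888 for P2ry12, 4.443 for Ctsl and 4.09 for Ctsd. It was -14.35 for Itgal, -13.14 for Ms4a4c, -12.91 for Slc2a6, -12.15 for Ptpn7, -12.07 for Itgax, -11.02 for Ezr, -10.66 for Mrc1 and -3.694 for Hmgb2. Values beyond 10 rest on a group in which some pools had few or no reads and give no bound on the change.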

How the results depend on the processing

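Alternatives chosen only after the data were seen were the subsets without the cycling clusters or the disease-associated clusters, the microglia-like gate comparison within shared libraries or without the block, and the age comparison without the P7 cortex pair, in which 32 of 80 cells of the P7 pool had failed quality control. That last one equals leaving out CTX (32 genes). Over all settings, 181 of 275 counts and shares stayed near the reported value, 91 moved and 3 reversed. Of 3208 values of named genes and lists, 2352 stayed on their side of the threshold, 716 lost their call and 33 reversed, and the rest gained one. With another scaling (RLE) 8 of 8 counts stayed within 1.5 times of the reported one. Counts rest on 5 region pairs, and in simulated data edgeR missed most 4-fold changes in CD45hi pools, so genes that did not pass are not shown to be unchanged. The pairing by region comes from the labels. Not run were the age test within border-macrophage-like cells and its alternatives (only the choroid plexus had 10 such cells at both ages), all cells for the microglia-like class, and a 1.5-fold minimum in the joint region test. Unless said, the cause was not tested.

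DESeq2 called 1444 genes by age in CD45low, 3184 by age in CD45hi, 891 by gate at P7, 2998 by gate at P60, 2219 in the interaction, 32 by region, 1024 for the choroid plexus and 451 within microglia-like cells. It also made more false calls in simulated data. limma on the mean CPM per cell called 728, 1189, 345, 1694 and 452 genes in the first 5 of these, 484 for the choroid plexus and 42 within microglia-like cells. A minimum change of 1.5-fold left 30 genes by age in CD45low, 22 in CD45hi and 0 within microglia-like cells (edgeR). Without the paired region block the counts were 358 by age in CD45low, 587 in CD45hi (61 of the reported calls among them), 1.4e+02 by gate at P7 (68), 860 at P60 (487) and 1 within microglia-like cells. Equal numbers of cells per pool (28) gave 32 genes by age in CD45low, 34 in CD45hi and 15 by gate at P7. Without a filter on low counts 1.4e+02 genes passed between the gates at P7. In microglia-like cells without the S phase and the G2 and M phase clusters 40 genes passed by age in CD45low (38 of the reported calls), with fewer cells per pool. With the choroid plexus added as a region 9 genes passed by age in CD45hi. Where both gates shared a library 29 genes passed at P7, 23 at P60 and 2 within microglia-like cells, with fewer pools. Within that class 6 genes passed without the cycling cluster and 0 without the disease-associated clusters. For E14.5, 3 genes met the rule of size in microglia-like cells only and 297 in the library with P7 cells only.

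With an estimated correlation the numbers of lists called were 0 by age in CD45low, 0 by age in CD45hi, 0 by gate at P7, 1 at P60, 0 in the interaction, 0 in each region, 3 for the choroid plexus and 0 within microglia-like cells. With fry, which tests the list by itself, they were 8 by gate at P7, 5 in the interaction, 3 for CB and 0 for CTX, HIP, STR and OB, 7 for the choroid plexus and 4 within microglia-like cells. The disease-associated gate difference at P60 was 8.58 points with 1 gene fewer.

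Reversed values were small or not called. Cx3cr1 by age in CD45low was 0.04657 with limma, 0.04662 without the paired block, 0.01726 without the disease-associated clusters and 0.009654 without the S phase and the G2 and M phase clusters. Csf3r by gate at P60 was -0.01221 without a filter, -0.005613 with all cells and -1.359 in 1 library. Ccr2 in the interaction was -0.2848 with DESeq2 and -0.7486 with limma, and Spp1 there 0.9288 with limma. Mki67 within microglia-like cells was 0.4087 without the disease-associated clusters. The oxidative phosphorylation list in the interaction had a fry p of 0.881 in the other direction. The border-macrophage-like share by age was -0.0518 points at resolution 0.4, -0.421 at 1.2 and -1.41 with 1000 variable genes.

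Leaving out 1 region at a time gave 10 to 52 genes by age in CD45low, 0 to 1.2e+02 in CD45hi, 25 to 90 by gate at P7, 213 to 350 at P60, 39 to 239 in the interaction, 14 to 94 for the choroid plexus and 0 to 7 within microglia-like cells. Log2 changes that crossed 0 were, in the interaction, Ccr2 (-1.703 to 4.465) and Mcm3 (-0.429 to 1.122), by age in CD45low Cx3cr1 (-0.1653 to 0.1381), by gate Mcm3 at P7 (-0.6258 to 0.1389) and Csf3r at P60 (-0.3206 to 0.3141), and Cx3cr1 within microglia-like cells (-0.2793 to 0.05046). For the choroid plexus, where each of its own pools was left out in turn as well, they were Cd74 (-4.322 to 0.8391), Fos (-3.582 to 0.07024), Mki67 (-2.488 to 1.163), P2ry12 (-1.091 to 2.392), Sall1 (-4.331 to 8.65), Spp1 (-2.73 to 0.4186) and Tmem119 (-0.496 to 2.53). None of these passed in the full set.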

Other observations

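No test of this part was chosen only after its result was seen, but how the tests on Xist and on neuron transcripts were judged was revised once their values were known. In the E14.5 pool, set beside the mean of the 10 postnatal CD45low pools, 8 border macrophage genes had a median log2 ratio of 0.64 (5 higher, percentile 98.7 of random lists) and 18 genes of lipid handling 0.43 (11 higher, percentile 98). Inflammatory cytokine and chemokine genes were low (-1.68, 0 of 13 higher), as were complement genes (-1.04, 2 of 14 higher), MHC class I genes (-1.03, 2 of 10 higher) and myeloid transcription factor genes (-0.77, 2 of 18 higher).

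In choroid plexus pools, S phase and G2 and M phase genes were higher at P7 than at P60 (median log2 ratios 1.12 and 1.23, 14 of 16 and 12 of 15 genes), although Mki67 was at 32.46 CPM at P7 (plates at 1.757 and 80.71) and 59.3 at P60. Higher at P7 were also 64 of 69 oxidative phosphorylation genes (0.77). Dendritic cell genes (-2.13, 2 of 7 higher), inflammatory genes (-0.99, 4 of 13 higher) and epithelial genes (-1.09, 3 of 8 higher) were lower at P7. In the interaction, Itgax, the integrin CD11c, was at 100.7 CPM in P60 CD45hi and 0 in P60 CD45low pools, but at 89.19 and 21.33 at P7. Ctsl, the protease cathepsin L, was at 182.6 and 1237 at P60 and at 2611 and 1707 at P7.

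Xist reads were found in 35.2% of E14.5 cells (50 cells), in 1 of 978 P7 cells and in 1 of 696 P60 cells. Cells of female embryos may have entered the E14.5 pool, although the series describes male animals. Of the E14.5 cells with Xist, 2% (1 of 50, 0.0506% to 10.6%) carried a Y-linked transcript, against 10.9% (10 of 92, 5.34% to 19.1%) of those without, with Ddx3y, Eif2s3y, Kdm5d and Uty read. These values met the bound written beforehand for cells of female embryos. The intervals overlap, however, and Y-linked transcripts were found in only 41.2% of P7 and 28.1% of P60 cells without Xist. The Y-linked counts therefore do not decide it.

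An unnamed cluster led by Mtap1b and Meg3 held 88 of the E14.5 cells and 13 of 76 P7 CD45low cells of CB. Neuronal RNA in sorted cells may be the source of these transcripts, but the test did not show it. Of 6 neuron transcripts, only 1 (Stmn2, 7.95% against 3.7% at E14.5 and 15.4% against 0% in P7 CB) was found in more cells of the cluster than of the other cells in both pools. This fell on the side written beforehand as against neuronal RNA. That bound could not decide, because the 6 transcripts were in 0% to 15.4% of cells, near the floor of detection.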
